A study of Mus musculus with 4 samples.

How the data were processed

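The study measured total RNA of pooled whole lungs of C57BL/6J mice on 4 oligonucleotide arrays, 1 per pool. The groups, per the labels, were unexposed lungs and lungs taken 6, 18 and 90 h after an aerosol of hexamethylene diisocyanate at 10 mg per cubic metre. The unexposed sample is titled with 0 h. The number of mice per pool, the length of exposure and the hour of day at collection are not given in the sources used here.

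The authors deposited 1 intensity per probe set and array, on a linear scale. The software, background correction and scaling behind these deposited intensities are not given in the sources used here. The values contain exact zeros, 184, 102, 105 and 126 in the unexposed, 6, 18 and 90 h pools, and no values below 0. Negative values, if any arose, therefore had been set to 0 or left out before deposit. A probe set summarises several probes for 1 transcript, and dim probe sets are close to background, so small intensities carry little information on level. Detection calls were not used here.

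The table held 12488 probe sets, of which 66 were controls. Names came from the platform annotation, updated through the gene identifier, which changed 0 symbols. Of the other 12422 probe sets, 10833 had 1 gene symbol, 396 had several and 1193 were not listed. Probe sets with several symbols or none were left out of gene counts. This left 8251 genes, 2073 of them with more than 1 probe set.

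Each array was scaled so that its mean after trimming 2% at each end equalled the mean of the 4 arrays. The scale factors were 1.07, 0.992, 0.970 and 0.972. Scaled values under the 40th percentile of all scaled values, 77.7 units, were set to that floor, and log2 was taken. Each gene was represented by its probe set with the highest mean. A gene at the floor on 1 of 2 arrays gives a bound, written as at least N-fold, and at the floor on both no fold. The floor shortens differences of dim genes. The 9 bacterial spike-in probe sets, which had no part in the scaling, had median log2 differences from the unexposed array of -0.11, 0.14 and 0.36 at 6, 18 and 90 h.

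Each time was compared with unexposed lungs, and each time with the one before. With 1 array per group there are no replicates and no test was made. Genes were counted at a threshold of 2-fold. As a yardstick, the noise of a probe set was estimated from the disagreement between probe sets of the same gene, with robust SDs of 0.26, 0.26 and 0.24 log2 units at 6, 18 and 90 h against unexposed. Then 200 sets of unchanged pools were simulated with it. This leaves out variation between animals, pools and hybridisations, so chance may exceed the simulated counts. The noise came only from probe sets above the floor on both arrays and without a suffix that marks possible cross-hybridisation. The counts include both other kinds. Genes shared between times were set beside the simulated sharing and beside that of independent lists.

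A set of 42 gene lists, for pathways and for cell types of lung, blood and neighbouring tissue, was fixed before the data were examined, as were the rules and all but 1 of the alternatives. For each list the median log2 difference over compared genes was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A median at or above the 97.5th percentile is called higher, and one at or below the 2.5th percentile lower. Lists with under 5 compared genes got no percentile. This describes these arrays, since genes of a list do not vary independently. Over 209 list comparisons, some calls come by chance alone.

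The genes named follow a fixed rule. Per time these were the 8 highest and 8 lowest differences measured on both arrays and the 3 largest bounds in each direction. Up to 4 members with the largest differences were named per list, as were the 4 genes furthest above and below all other pools among genes above the floor in all 4. Unnamed complementary DNAs were passed over. Results that contain other genes say so.

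The code was tested on simulated data for the comparison of 6 h with unexposed lungs, with 200 of 6286 genes changed. Of higher genes, 4% were found past 2-fold at a true fold of 1.5, 84% at 2.5 and 100% at 3 and 4. Of lower genes it found 8%, 60%, 52% and 72%, since the floor cuts short the decrease of dim genes. Of 6086 unchanged genes 22 passed 2-fold. Of 100 unshifted lists 2 fell outside the central range, and 100 of 100 lists shifted by 0.3 were called.

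The alternatives were other scalings (none, median, quantile, and cyclic loess with limma), floors at the 25th and 60th percentile, and a pseudocount in place of the floor. Others were the mean over all probe sets of a gene, leaving out probe sets whose suffix marks possible cross-hybridisation, and thresholds of 1.5-fold and 3-fold. For lists these were the mean over members, members above the floor on both arrays, and, chosen after seeing the data, leaving out genes shared with another list. Sharing between times was also computed against the median of the other 3 arrays. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.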

Results

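Gene expression was measured in whole lungs of C57BL/6J mice, an inbred laboratory strain, with and without inhalation of hexamethylene diisocyanate (HDI). HDI is a reactive chemical used to make polyurethane paints and coatings, and its vapour and aerosol irritate the airways. Lungs were pooled into 4 samples, each read on 1 Affymetrix MG_U74Av2 array: unexposed lungs, and lungs taken 6, 18 and 90 h after an aerosol of 10 mg per cubic metre. The comparisons ask how the lung's transcripts differed from those of unexposed lungs at each time, and from each time to the next. With 1 array per pool there was no spread between replicates, so no difference below carries a p-value, and a fold describes these arrays rather than the exposure. The number of arrays limits the precision. All 3 comparisons with unexposed lungs share the same array.

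The 4 arrays were alike in median signal. Their deposited intensities had medians of 97.7, 106, 106 and 108 in the unexposed, 6, 18 and 90 h pools, and 5712, 5690, 5664 and 5733 genes lay above the floor. Of 8251 genes with a named probe set, 6286 were above the floor on at least 1 array. The 3' to 5' signal ratio of Gapdh, a sign of RNA integrity, was 1.21, 1.16, 1.12 and 1.22. The ratio for beta-actin was 1.5, 1.30, 1.36 and 1.55. The 9 reference genes compared had median log2 differences from the unexposed pool of -0.06, 0.10 and 0.02 at 6, 18 and 90 h. Among them Actb had log2 differences of -0.39 and -0.71 at 6 and 18 h by a dim probe set, while the array's 3' beta-actin control probe set read 8155, 7610 and 7917 in the unexposed, 6 and 18 h pools. The 3' Gapdh control probe set was less even, at 1860, 2105, 2973 and 2000 in the 4 pools. Pgk1, a glycolytic enzyme, was 1.70-fold higher at 18 h.

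The number of genes at least 2-fold away from the unexposed pool was highest at 6 h. At 6 h 131 genes were higher and 91 lower, at 18 h 96 and 57, and at 90 h 44 and 56. Pools simulated as unchanged, with noise taken from the disagreement between probe sets of the same gene, gave means of 10.5 to 11 genes per direction. That noise leaves out differences between animals and between pools. It also leaves out probe sets at the floor on either array and those marked for possible cross-hybridisation, which the counts include. Without marked probe sets 125 genes were higher and 70 lower at 6 h, 91 and 47 at 18 h, and 41 and 38 at 90 h. Of the 131 and 91 genes at 6 h, 33 and 18 were bounds, since 1 of the 2 arrays was at the floor.

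**Figure D1:**
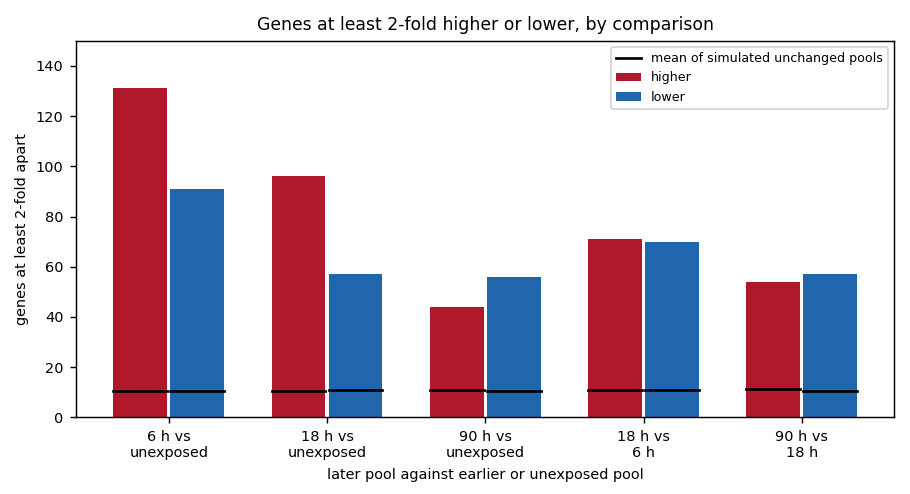
Number of genes at least 2-fold higher (red) or lower (blue) in the later pool of each comparison, with the mean of simulated unchanged pools as black lines. The bars run from 131 genes higher at 6 h to 44 genes higher at 90 h, against simulated means of 10.5 to 11.3.

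At 6 h the genes furthest above the unexposed pool were of several kinds. Mt2 and Mt1, the metallothioneins that bind zinc and cadmium, were 13.5-fold and 9.82-fold higher. Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, was 7.03-fold higher, Hmox1, which degrades heme, 5.62-fold, and Txnrd1, a thioredoxin reductase, 5.31-fold. Fkbp5, a glucocorticoid-induced co-chaperone of steroid receptors, was 6.73-fold higher, and Hspa1b, an inducible 70 kDa heat shock protein gene, 6.30-fold. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was 6.29-fold higher by its brightest probe set, and its other probe set gave a log2 difference of 0.59. Genes at the floor in unexposed lungs gave bounds: Acta1, the skeletal muscle actin, was at least 7.86-fold higher, Sfn, an epithelial 14-3-3 protein, at least 7.23-fold, and the kinase gene Map3k6 at least 5.56-fold.

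The genes furthest below the unexposed pool at 6 h were also of several kinds. Lhx6, a homeobox gene, was 5.93-fold lower, Dnajc1 4.11-fold, Fscn1, an actin-bundling protein of mature dendritic cells, 3.92-fold, and Kap 3.57-fold. Plac8 was 3.56-fold lower, Snn 3.21-fold, Aplf 3.20-fold and Cox4i1 3.17-fold, the last by a probe set whose suffix marks possible cross-hybridisation. Bounds came from Cyth2, at least 6.03-fold lower, the histamine receptor gene Hrh2, at least 5.78-fold, and Gbp2, an interferon-induced guanylate-binding protein, at least 3.21-fold. Lhx6, Dnajc1 and Hrh2 were low in all 3 exposed pools alike.

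Among the gene lists, the fasting and glucocorticoid response genes had the highest median at 6 h. Their median log2 difference was 1.03, 12 of 22 compared genes were at least 2-fold higher, and 21 of 22 were above 0. This list shares Mt1 and Mt2 with the metallothionein and zinc transporter list, whose median was 0.25 in 8 genes, with only these members past 2-fold. The adipocyte list was higher as well, with a median of 0.75 in 13 genes, though only Fabp4 (2.74-fold) passed 2-fold. Lpl, a lipoprotein lipase, was 1.87-fold higher, and Pck1 and Ucp1 were at least 1.87-fold and 1.81-fold higher. The glucocorticoid and adipocyte medians lay above those of all 10000 random lists of the same size and level. Of the 93 list calls made over the 5 comparisons, 59 held under every alternative that left at least 5 genes to compare.

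The antioxidant and stress lists moved with them. Of 24 genes of glutathione metabolism and the NRF2 antioxidant response, 6 were at least 2-fold higher and none lower (median 0.25), led by Gclc, Hmox1 and Txnrd1, with Srxn1 at least 5.08-fold higher. The glutathione S-transferases did not stand apart (median -0.08 in 15 genes). Genes of the unfolded protein and integrated stress response had a median of 0.74, with 5 of 14 past 2-fold. Ddit4 was 3.79-fold higher, Atf3 at least 3.73-fold, Atf4 2.16-fold and Ppp1r15a 2.10-fold. Among 10 p53 target genes (median 0.56), 4 were past 2-fold: Cdkn1a, Fas (at least 2.91-fold), Gadd45a (at least 2.82-fold) and Sesn1 (2.63-fold). Of 19 immediate early genes, which respond to stimuli within minutes, 7 were past 2-fold (median 0.72), with Egr1 2.99-fold, Fos 2.94-fold and Fosl1 at least 2.41-fold higher. The heat shock and chaperone list had a median of 0.34, with Hspa1b and Hspa1a past 2-fold. Both encode nearly the same protein, so their probe sets need not be independent. Hspa4 was 2.20-fold lower, but with all its probe sets averaged its log2 difference was 0.05.

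Epithelial injury and proteasome genes were also higher at 6 h. The list of transitional and injured epithelium genes had a median of 0.45, with 5 of 19 past 2-fold, led by Sfn, Cdkn1a, Plaur, the urokinase receptor (at least 3.52-fold), and Krt18, a keratin of simple epithelia (2.62-fold). Of 25 proteasome genes, 24 were above 0 and none passed 2-fold (median 0.35), with Psmd11 1.95-fold and Psmd14 1.83-fold higher. The circadian clock list was higher (median 0.30 in 14 genes), with Per1 2.08-fold and Cry1 1.93-fold higher. Dbp and Nr1d1 were 2.57-fold and 1.82-fold lower.

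Genes of immune cells were lower at 6 h. All 14 MHC class II and dendritic cell genes were below the unexposed pool (median -0.58), with Fscn1 3.92-fold, H2-Oa 2.16-fold, H2-DMa 1.68-fold and H2-Eb1 1.61-fold lower. Of 13 B cell and plasma cell markers 12 were not above 0 (median -0.54). Cd79a, part of the B cell receptor, was 2.72-fold lower, Ighm 2.32-fold and Fcer2a 2.01-fold, but with all its probe sets averaged Ighm had a log2 difference of -0.16. Of 19 interferon-stimulated genes 15 were not above 0 (median -0.52), with Irf7 at least 2.01-fold, Irf8 1.99-fold and Psmb8 1.72-fold lower. The T cell and NK cell markers had a median of -0.36 in 9 genes, none past 2-fold, and with the floor at the 25th percentile their median was 0.01. The 7 thymus and immature T cell genes had a median of -0.36, with 6 of 7 not above 0, and lay inside the random range with that floor. The macrophage and monocyte list did not stand apart (median -0.05 in 20 genes), nor did neutrophil markers (-0.12 in 12) or inflammatory chemokines and cytokines (-0.18 in 16). The array held 18 neutrophil markers and 34 chemokine and cytokine genes. Those not compared were at the floor in both pools, so nothing can be said of them. Among the chemokines Ccl5 was 2.34-fold and Cxcl12 2.03-fold lower.

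The 6 h counts depended on the floor more for lower than for higher genes. The 91 lower genes became 47 with the floor at the 60th percentile and 42 with a pseudocount in its place. Of 23 genes past 2-fold by 1 probe set that had a further measured one, 18 had the same sign by it and 9 passed 2-fold. The metallothionein list left its place outside the random range under 9 alternatives, the adipocyte list with the floor at the 60th percentile, and Cox4i1, Cxcl12 and Irf7 were under 2-fold with their probe sets averaged. So were Egr1, Fos, Atf3 and Krt18, with log2 differences of 0.79, 0.78, 0.79 and 0.69. A probe set at the floor on both arrays counts as no difference in such an average and lowers it by construction. This held for Cox4i1, which had no other probe set above the floor in either pool.

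Among genes measured on both arrays Lrg1 stood highest at 18 h. Lrg1, a leucine-rich glycoprotein of the acute phase, was 6.70-fold higher, Lcn2, which binds bacterial siderophores, 5.76-fold, and the protease inhibitor gene Serpina3n 4.16-fold. Tnc, the matrix glycoprotein tenascin C, was 5.06-fold higher and Timp1, an inhibitor of metalloproteinases, 3.97-fold. The second probe sets of Lcn2 and Tnc gave log2 differences of 1.84 and 1.44. With all probe sets of Timp1 averaged its log2 difference was 0.99, since its other probe set was at the floor in both pools. Mt2, Hspa1b and Mt1 remained 6.05-fold, 5.38-fold and 3.8-fold above the unexposed pool. Bounds came from Rpl39l, at least 10.6-fold higher, Acta1, at least 5.05-fold, and Emc10, at least 4.72-fold.

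Nr1d1, a nuclear receptor that represses clock genes, was 4.94-fold lower at 18 h, and Dbp, a clock-controlled transcription factor, at least 2.77-fold. Lhx6 was 5.86-fold lower, Cuta 3.93-fold, Batf 3.33-fold and Dnajc1 3.18-fold. Bcan was 3.15-fold lower, the T cell chemokine gene Ccl5 3.0-fold and Igfbp3 2.74-fold. Hrh2 and Elp5 were at least 5.78-fold and 3.49-fold lower.

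The transitional and injured epithelium list had the highest median at 18 h (0.95), with 9 of 20 genes past 2-fold and 19 of 20 above 0. Besides Tnc, its leading members were Sfn (at least 3.72-fold), the cornified envelope protein gene Sprr1a (2.70-fold) and Hbegf, an epidermal growth factor receptor ligand (2.65-fold). All 25 proteasome genes were above 0, with a median of 0.68 and 4 past 2-fold: Psma5 was 2.56-fold, Psmb3 2.55-fold, Psmd14 2.53-fold and Psmc2 2.0-fold higher. The heat shock and chaperone median was 0.54, with Cct3 2.19-fold and Hsph1 2.08-fold higher. The NRF2 list had a median of 0.54, with Gclc 2.35-fold, Gsr, glutathione reductase, 2.19-fold and Srxn1 at least 2.08-fold higher.

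Sterol synthesis genes joined them at 18 h. The lipid and sterol list had a median of 0.46, with 3 of 14 genes past 2-fold, all enzymes of the isoprenoid and sterol pathway: Idi1 (2.16-fold), Sqle (2.12-fold) and Fdps (2.06-fold). Hypoxia and glycolysis genes had a median of 0.35, with none of 17 past 2-fold and Ldha 1.76-fold higher. Oxidative phosphorylation genes had a median of 0.21, with 22 of 28 above 0. The immediate early list had a median of 0.40, with Junb 2.33-fold and Egr1 2.20-fold higher, and the unfolded protein and integrated stress response list one of 0.40, with none past 2-fold. The fasting and glucocorticoid list had a median of 0.29, with 6 of 20 at least 2-fold higher and 1 lower, but -0.03 without genes shared with other lists. The clock list's median was 0.25 while the mean of its members was -0.15, since Nr1d1 and Dbp lay far below the rest, and its place was lost under 6 alternatives. Matrix-degrading proteases and inhibitors had a median of 0.29, led by Timp1 and Mmp3 (2.5-fold), a place that was lost under 6 alternatives.

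Among acute phase and airway defence genes at 18 h, 5 of 21 were at least 2-fold higher and 1 lower, and the list's median of 0.05 did not stand apart. Lymphocyte lists were lower, with medians of -0.37 in 13 B cell genes and -0.41 in 9 T cell and NK cell genes, none past 2-fold. The second of these lay inside the random range with the floor at the 25th percentile. The thymus list had a median of -0.52 in 7 genes, with Ptcra 1.89-fold and Rag1 1.73-fold lower. MHC class II and interferon medians were -0.27 and -0.33, with H2-Ab1 1.82-fold, Gbp2 2.14-fold and Igtp 2.09-fold lower. Mast cell and eosinophil markers had a median of -0.34, led by Mcpt8 (1.92-fold lower), by a probe set whose suffix marks possible cross-hybridisation. Without such probe sets the log2 difference of Mcpt8 was -0.30 at 6 h and at 90 h, a bound set by the floor in both later pools.

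Club cell, P450 and heart and skeletal muscle genes were lower at 18 h. The cytochrome P450 and xenobiotic list had a median of -0.35 and the club cell list one of -0.35, and these lists share 4 genes. Cckar was 2.24-fold and Cyp2f2, a P450 of club cells, 1.56-fold lower, while Aldh3a1 was 1.97-fold higher. Heart and skeletal muscle genes, included as a possible sign of neighbouring tissue, had a median of -0.33 in 21 genes. Acta1 was the only member past 2-fold, and it was higher. Whole lungs do not show which tissue these transcripts came from. Mitosis genes had a median of -0.30 in 14 genes, with Kif22 1.74-fold lower.

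The split between higher and lower genes at 18 h depended on scaling. Of the genes past 2-fold, 62.7% were higher after scaling and 81.6% with deposited values unscaled, with 32 lower genes in place of 57. Unscaled values moved the median log2 difference of all genes from -0.01 to 0.12. Of 8 genes past 2-fold by 1 probe set, 7 had the same sign and 1 passed 2-fold by another. At least 1 alternative also placed the P450, muscle, mast cell and mitosis lists inside the random range. Averaging probe sets brought Bcan, Cuta, Dnajc1, Cct3, Egr1, Fdps and Srxn1 under 2-fold. Of these, Bcan, Cuta and Dnajc1 had no other probe set above the floor in either pool, so their fall follows from the averaging.

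At 90 h genes of macrophages, cell division and matrix were higher than in unexposed lungs. Mt2 and Mt1, far higher at 6 h, had log2 differences of -0.17 and 0.17. Birc5, an inhibitor of apoptosis also needed in cell division, was at least 6.81-fold higher, Cdc20, which activates the anaphase-promoting complex, 2.70-fold, and the cyclin gene Ccnb2 2.46-fold. Ccl6, a macrophage chemokine, was 3.24-fold higher and Tnc 2.70-fold, though the other Tnc probe set gave a log2 difference of 0.46. Ssbp2 was 4.03-fold higher, from 78.3 units in the unexposed pool, just above the floor of 77.7. Rgs11 was 3.11-fold and Chmp2a 2.52-fold higher. Ankzf1 was 2.97-fold higher by a probe set whose suffix marks possible cross-hybridisation, and its other 2 probe sets gave a median log2 difference of -0.05. Emc10 and Omt2b were at least 5.10-fold and 4.81-fold higher.

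Nr1d1 was 7.85-fold lower at 90 h, below the 18 h level. Lhx6 was 5.67-fold lower, Aplf 5.37-fold, the muscle oxygen carrier gene Mb 4.24-fold, Mep1a 3.51-fold and Dnajc1 3.50-fold. P4hb was 3.54-fold and Olfr157 3.37-fold lower by cross-hybridisation-marked probe sets, and the other P4hb probe set gave a log2 difference of -0.02. C1ql1, Hrh2 and Elp5 were at least 6.32-fold, 5.78-fold and 3.49-fold lower.

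Macrophage and monocyte genes had the highest list median at 90 h, 0.56, with 18 of 21 above 0 and 3 past 2-fold. Ctsk, a cathepsin, was at least 3.10-fold higher, Chil3, a chitinase-like protein, 2.16-fold, Mrc1, the mannose receptor, 2.04-fold and Ctss 1.96-fold. With the floor at the 60th percentile Ctsk and Mrc1 had log2 differences of 0.81 and 0.80. With a pseudocount Mrc1 and Chil3 had 0.70 and 0.98. Mitosis genes had a median of 0.34, with 17 of 21 above 0 and 3 past 2-fold, and Mki67 was at least 1.99-fold higher. DNA replication genes had a median of 0.27 in 13 genes, none past 2-fold. Of 31 extracellular matrix and fibroblast genes 28 were above 0 (median 0.29), with Tnc, Eln, which encodes elastin, 2.25-fold, and the crosslinking enzyme gene Loxl1 1.61-fold higher. Matrix-degrading proteases and inhibitors had a median of 0.33.

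Several epithelial and stress lists were also above the unexposed pool at 90 h. Alveolar type II cell markers had a median of 0.33, with 10 of 14 above 0 and Muc1 1.81-fold higher, while Cd36 was 2.0-fold lower by a probe set marked for cross-hybridisation, and had a log2 difference of 0.45 without such probe sets. Immediate early genes had a median of 0.32, with Fos 2.33-fold higher, heat shock genes one of 0.29, with Hspa1b 2.09-fold higher, and injured epithelium genes one of 0.29. Lipid and sterol genes had a median of 0.27 and complement and coagulation genes one of 0.22, the latter lost under 7 alternatives.

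The lower lists at 90 h included those of muscle, B cells and club cells. Heart and skeletal muscle genes had a median of -0.42, with 19 of 20 not above 0 and Mb the only one past 2-fold. Smooth muscle and pericyte genes had a median of -0.40, with Tpm2 1.98-fold and Myh11 1.60-fold lower. B cell genes had a median of -0.40, with Spib 2.06-fold lower. Sdc1, on that list as a plasma cell marker, was 1.83-fold higher, and whole lungs do not show which cells it came from. The club cell median was -0.33, with Reg3g 1.75-fold lower and Scgb1a1, the main club cell secretory protein, 1.33-fold lower. The P450 list had a median of -0.28, mast cell and eosinophil genes -0.22 and red blood cell genes -0.21.

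At 90 h the 44 higher genes became 91 with the floor at the 25th percentile and 22 with it at the 60th. Of the genes past 2-fold 44.0% were higher after scaling and 61.2% with unscaled values, which moved the median of all genes from 0.03 to 0.16. Only 5 genes past 2-fold by 1 probe set had a further measured one: all 5 had the same sign by it and 1 passed 2-fold. The correlation across genes between log2 differences of probe sets of the same gene was 0.55 at 6 h, 0.44 at 18 h and 0.30 at 90 h. At least 1 alternative placed the DNA replication, club cell, sterol, protease, mast cell, red blood cell and injured epithelium lists inside the random range. Averaging probe sets brought Rgs11, Dnajc1, Ankzf1, P4hb, Tnc, Spib and Fos (0.61) under 2-fold. Of these, Rgs11 and Dnajc1 had no other probe set above the floor in either pool, so their fall follows from the averaging. With the floor at the 60th percentile Cdc20 and Ccnb2 had log2 differences of 0.76 and 0.61.

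**Figure D2:**
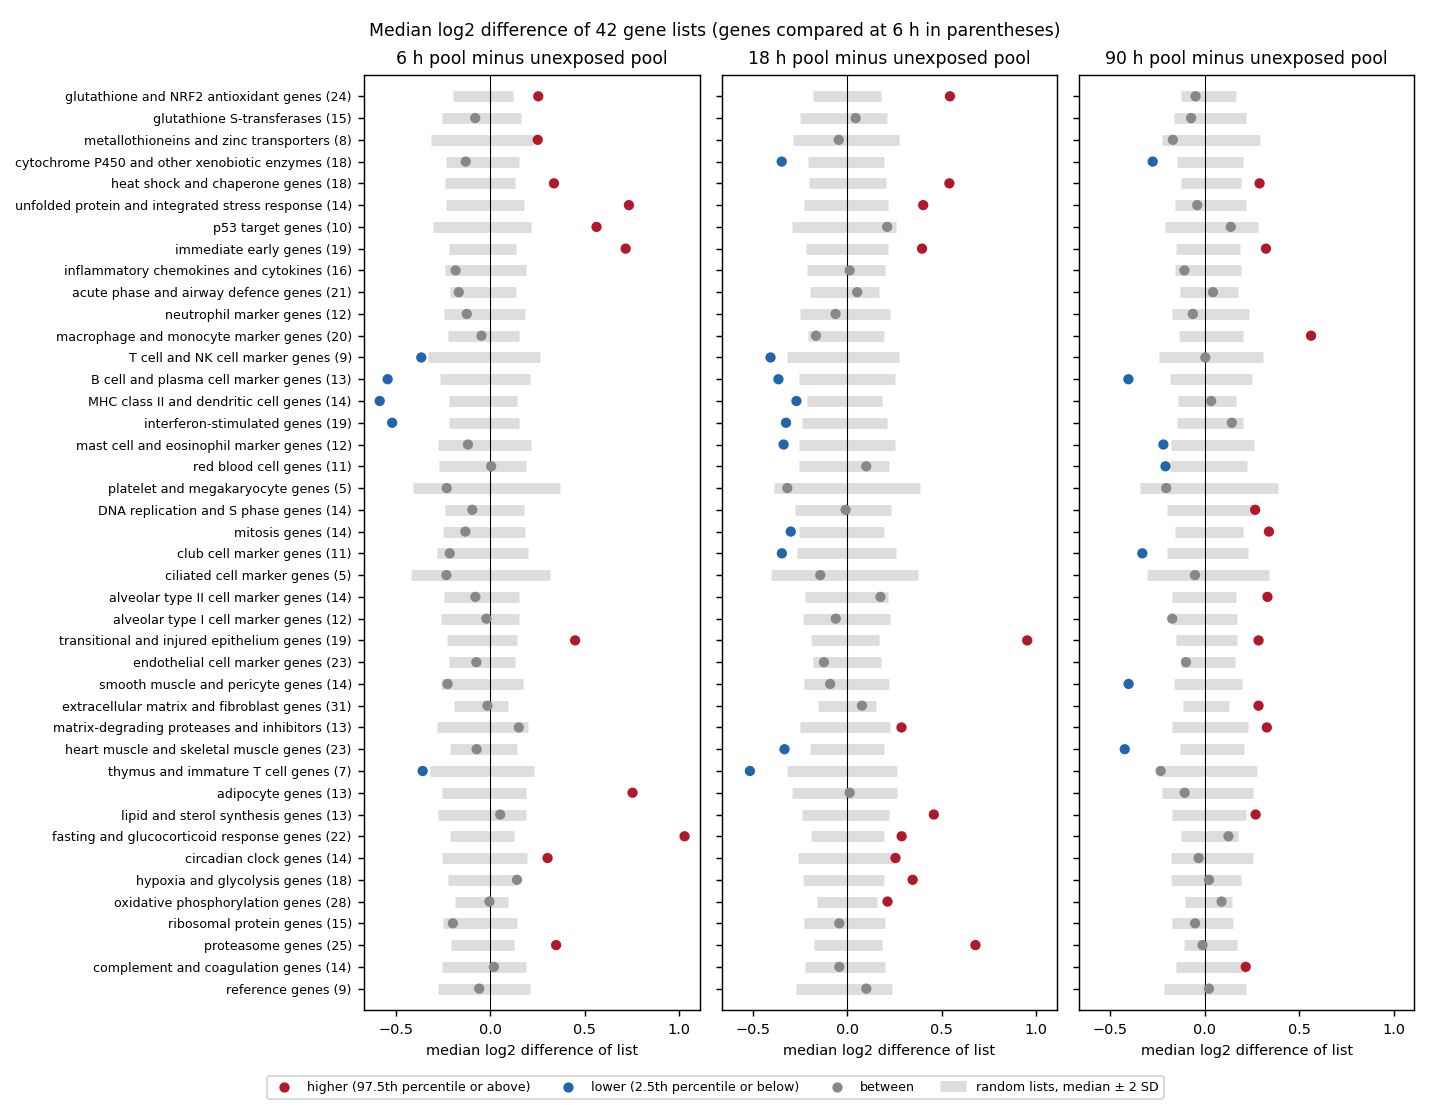
Median log2 difference of each of the 42 gene lists between the 6, 18 or 90 h pool and the unexposed pool (horizontal axis), with the number of genes compared at 6 h in parentheses. Points are coloured by their place among random lists, and grey bars span the random median plus and minus 2 SD; the glucocorticoid list reaches 1.03 at 6 h, injured epithelium 0.95 at 18 h and macrophages 0.56 at 90 h.

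From 6 to 18 h, 71 genes were at least 2-fold higher and 70 lower, without use of the unexposed array. The fasting and glucocorticoid list was lower at 18 h than at 6 h (median -0.83, 9 of 22 past 2-fold lower and 1 higher), as were metallothionein (-0.43), adipocyte (-0.44), p53 (-0.38), clock (-0.37), immediate early (-0.36), integrated stress (-0.30), muscle (-0.24) and NRF2 (-0.18) lists. Against unexposed lungs the NRF2 median had been higher at 18 h (0.54) than at 6 h (0.25), while the mean over members was lower (0.38 against 0.64). Acute phase and airway defence genes were higher at 18 h (median 0.60, 4 of 19 past 2-fold). Lipid and sterol (0.41), proteasome (0.37), oxidative phosphorylation (0.23), glutathione S-transferase (0.22) and interferon (0.20) lists were higher too. The interferon list was inside the random range under 4 alternatives, the glutathione S-transferase list under 3, the p53 list with both other floors, and the metallothionein, adipocyte and integrated stress lists under 1 each.

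From 18 to 90 h, 54 genes were at least 2-fold higher and 57 lower. All 25 proteasome genes were lower at 90 h (median -0.66), and injured epithelium (-0.58), NRF2 (-0.36), acute phase (-0.35), unfolded protein (-0.35), glucocorticoid (-0.33), heat shock (-0.33) and sterol (-0.28) lists were lower. Red blood cell (-0.28), glutathione S-transferase (-0.26), clock (-0.25), smooth muscle (-0.24), metallothionein (-0.23), oxidative phosphorylation (-0.22) and hypoxia (-0.20) lists were lower as well. Macrophage genes were higher, with a median of 0.62 and 4 of 20 past 2-fold, and so were all 21 mitosis genes (median 0.45). Interferon (0.33, with 19 of 20 genes above 0), MHC class II (0.29), neutrophil (0.29), complement (0.24) and matrix (0.15) lists were higher at 90 h than at 18 h. The neutrophil, complement, sterol and metallothionein lists were inside the random range under 2 alternatives each, and the glucocorticoid, glutathione S-transferase, clock and red blood cell lists under 1. Without shared genes the glucocorticoid median was -0.06 and the neutrophil median 0.09, and with the floor at the 60th percentile the sterol median was -0.01.

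Genes past 2-fold were shared between times more often than in simulated unchanged pools that share the unexposed array. For higher genes, 37 were shared by 6 and 18 h, 7 by 6 and 90 h and 9 by 18 and 90 h, against simulated means of 2.49, 2.43 and 2.41. Lists drawn independently would share 1.94, 0.715 and 0.521. For lower genes the numbers were 23, 25 and 27, against simulated means of 3.24, 3.27 and 3.29 and independent values of 0.879, 0.865 and 0.540. Across all 3 times 6 higher and 17 lower genes were shared, against simulated means of 1.82 and 2.25. The genes shared by all 3 times are, by construction, those that set the unexposed pool apart. Against the median of the other 3 arrays, 18, 0 and 1 higher and 3, 0 and 2 lower genes were shared. The shared control cannot be split, so part of the excess may come from that array. The covariance of log2 differences across 5848 genes was 0.112 for 6 and 18 h, 0.0615 for 6 and 90 h and 0.0941 for 18 and 90 h, where sharing the array alone gave 0.0355, 0.0358 and 0.0359. The correlations were 0.614, 0.387 and 0.630, where sharing the array alone gave 0.502, 0.506 and 0.508, so that of 6 and 90 h lay below it.

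Counts that treat all pools alike set the 6 h pool apart. In it, 43 genes were at least 2-fold above and 25 at least 2-fold below each of the other pools, against simulated means of 2.32 and 2.04. The numbers were 17 and 6 for the unexposed pool, 13 and 3 for the 18 h pool and 22 and 8 for the 90 h pool. Simulated means for these pools were 1.82 to 2.43. The 3 genes lower at 18 h lay inside the central range of simulated counts (0 to 5.025), and the 6 lower in unexposed lungs just past it (0 to 5). Among genes above the floor in all pools, highest above the rest at 6 h were Cacna2d3 (4.25-fold), Zbtb16, a glucocorticoid-induced transcription factor (4.18-fold), Hmox1 (3.69-fold) and Cdh4 (3.43-fold), each against the nearest other pool. Furthest below were Fscn1 (3.79-fold), Cox4i1 (3.02-fold), Tex261 (2.92-fold) and Ckb (2.43-fold). At 18 h Timp1 (3.57-fold), Aimp2 (3.10-fold), Lcn2 (3.06-fold) and Axl (2.41-fold) stood highest, and Cuta (3.06-fold), Dusp8 (2.45-fold), Slc4a5 (2.08-fold) and Igfbp3 (1.83-fold) lowest. At 90 h, again leaving out genes at the floor in any pool, such as Birc5, these were Rgs11 (3.11-fold), Ankzf1 (2.97-fold), Ghrh (2.24-fold) and Ccl6 (2.17-fold) above, and Mep1a (3.51-fold), Mb (2.82-fold), P4hb (2.62-fold) and Cldn6 (2.12-fold) below.

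The unexposed array stood alone for Lhx6, with a scaled intensity of 699 against 118, 119 and 123 in the exposed pools. Dnajc1 was 3.18-fold, Batf 2.73-fold and Olfr157 2.63-fold above the nearest exposed pool. The other Dnajc1 probe set was below the floor on all 4 arrays. Among the 17 genes higher in the unexposed pool alone, only Ung and Bphl, not named by the rule, had another probe set above the floor on all arrays. By it Ung read 183 in unexposed lungs against 143, 144 and 165 at 6, 18 and 90 h. Bphl read 219 against 143, 168 and 225, so neither repeated the difference of 2-fold. Among genes above the floor in all pools, lowest in unexposed lungs were Chmp2a (2.47-fold), Hspa1b (2.09-fold), Fos (1.97-fold) and Cdkn1a (1.92-fold).

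**Figure D3:**
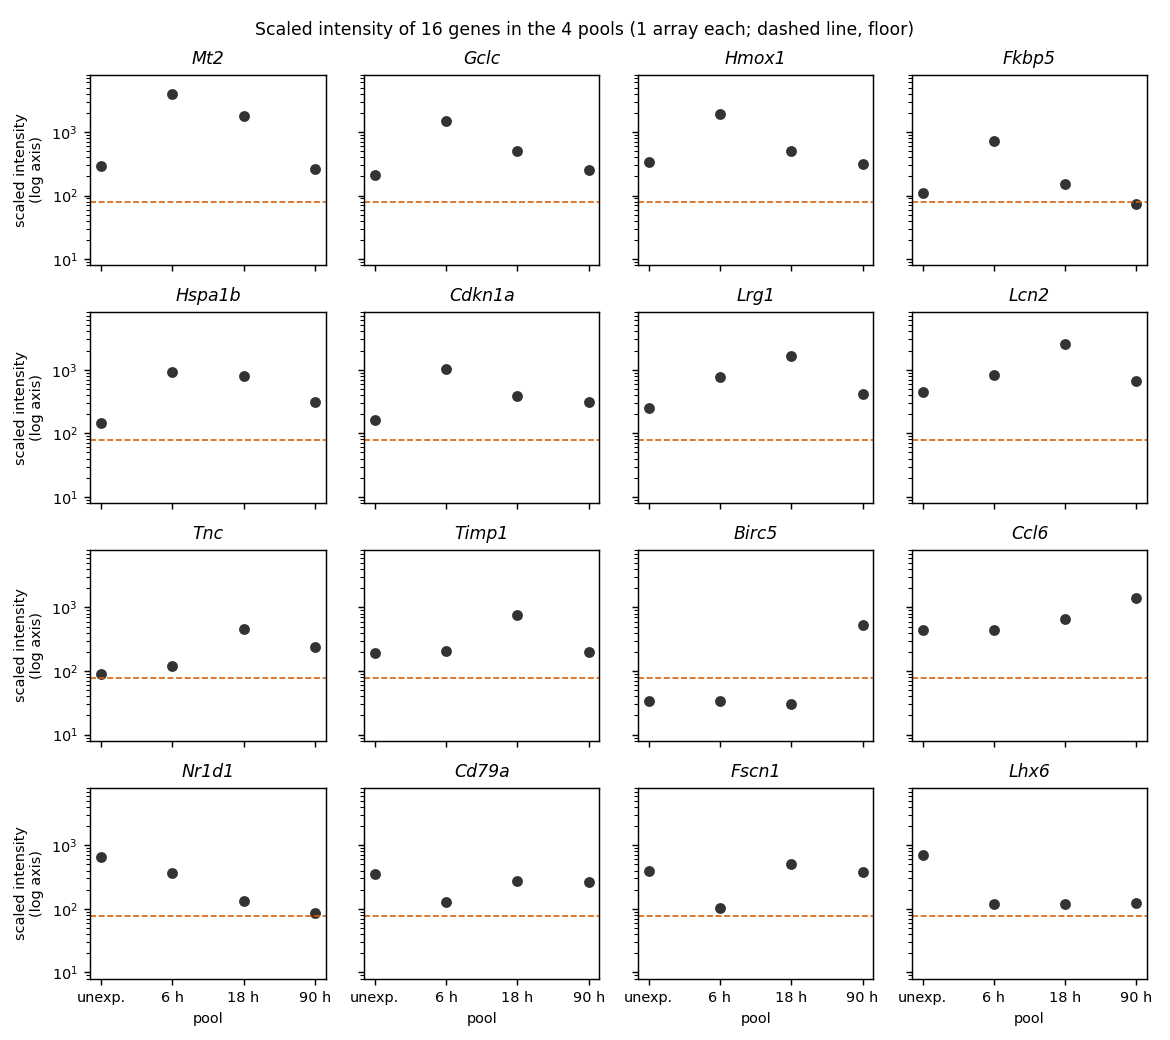
Scaled intensity (log axis) of 16 genes in the 4 pools, 1 array each, with the floor as a dashed line. Mt2 was at 293, 3956, 1774 and 261 in the unexposed, 6, 18 and 90 h pools, Nr1d1 at 663, 364, 134 and 84.5, and Birc5 was above the floor at 90 h alone among these pools.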

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

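The genes and list in the next paragraph were picked because they lay at least 2-fold, or outside the random range, on opposite sides of the unexposed pool at 2 times. With 1 array per pool none of these differences was tested. No group had enough samples for a search for outlying samples.

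Zbtb16, a transcription factor induced by glucocorticoids, had log2 differences of 2.06 at 6 h, -1.08 at 18 h and -1.30 at 90 h, the last -0.72 with all its probe sets averaged. Lyve1, a receptor of lymphatic endothelium, stood at 1.57 at 6 h and -1.05 at 90 h, the last -0.79 with a pseudocount. Nrep stood at -1.33 at 18 h and 1.03 at 90 h, and Sprr1a, a cornified envelope protein, at 1.43 at 18 h and at -1.18 at 90 h, a bound set by the floor, which was -0.35 with the floor at the 60th percentile and -0.92 with a pseudocount. The mitosis genes had a median log2 difference of -0.30 at 18 h and 0.34 at 90 h.

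Probe sets outside the gene comparisons also differed. The array's mouse Fas control probe set, not used for scaling or counts, had a log2 difference of 1.27 at 6 h, and Fas in the p53 target list was at least 2.91-fold higher. Of 1589 probe sets with several listed genes or none, 864, 838 and 849 could be compared at 6, 18 and 90 h. Among them 18, 14 and 2 were at least 2-fold higher than in unexposed lungs.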

How the results depend on the processing

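No paired analysis was possible because each group has 1 array. For the same reason no array could be left out and no other split of the samples could be made. Of 278 counts under alternatives, 168 stayed within 1.5 times their main value. The others are given here. The cause was not tested, except where a stricter threshold or floor leaves fewer genes by construction. A pseudocount added to both values also shortens, by construction, folds between values above the floor. Averaging takes in probe sets at the floor on both arrays, which count as no difference.

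With a 1.5-fold threshold, 432 genes were higher and 366 lower at 6 h than unexposed, 410 and 370 at 18 h, and 206 and 296 at 90 h. From 6 to 18 h there were 320 and 286, and from 18 to 90 h 220 and 237. Above and below all other pools there were 105 and 45 genes for unexposed lungs, 144 and 92 for 6 h, 54 and 30 for 18 h, and 67 and 33 for 90 h. With a 3-fold threshold the counts against unexposed were 43 and 14, 24 and 9, and 13 and 11. The steps between times gave 13 and 18, and 13 and 18. The pools alone gave 3 and 3, 11 and 3, 5 and 1, and 7 and 2.

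With the floor at the 25th percentile, 153 genes were higher at 18 h, and 91 higher and 87 lower at 90 h. From 18 to 90 h 90 were lower. Lower in the unexposed pool than in all others were 22 genes, 6 in the 18 h pool and 17 in the 90 h pool, and 21 were higher at 18 h. Higher at 6 and 18 h were 60, at 6 and 90 h 28, at 18 and 90 h 34, and at all 22. With the floor at the 60th percentile, 47 were lower at 6 h, 29 at 18 h and 25 at 90 h, and 22 higher at 90 h. From 6 to 18 h 38 were higher, and from 18 to 90 h 34 higher and 37 lower. Set apart from all others were 9 higher and 3 lower in unexposed lungs, 14 lower at 6 h, and 13 higher and 5 lower at 90 h. Shared higher genes numbered 4, 3 and 3 for 6 and 90 h, 18 and 90 h and all times, and shared lower genes 13, 11, 12 and 9 for 6 and 18 h, 6 and 90 h, 18 and 90 h and all.

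With a pseudocount in place of the floor, 42 genes were lower at 6 h, 60 higher and 21 lower at 18 h, and 28 higher and 32 lower at 90 h. From 6 to 18 h there were 28 and 42, and from 18 to 90 h 32 higher. Set apart were 8 higher in unexposed lungs, 24 higher and 8 lower at 6 h, and 11 higher at 90 h, and shared lower genes numbered 9, 11, 11 and 8. With the mean of all probe sets, 36 genes were lower at 90 h, 10 stood higher in unexposed lungs alone, 15 lower at 6 h alone and 1 lower at 18 h alone, and shared lower genes numbered 14, 16, 17 and 10. Without probe sets marked for cross-hybridisation, 11 stood higher in unexposed lungs alone, 12 lower genes were shared by 6 and 90 h and 11 by all times.

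Without scaling, 32 genes were lower at 18 h and 13 lower in unexposed lungs alone. Shared higher genes numbered 56, 13, 19 and 13, and shared lower genes 15 for 6 and 18 h and 15 for 18 and 90 h. Against the median of the other 3 arrays, shared higher genes numbered 18, 0, 1 and 0 and shared lower genes 3, 0, 2 and 0, a measure that by construction counts a gene less often when several pools move together. Median, quantile and cyclic loess scaling kept every count within 1.5 times.

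Of 93 calls on gene lists, 59 held under every alternative that left enough genes and 34 were lost under at least 1. With the floor at the 60th percentile 4 calls had too few genes to be judged. Over members above the floor on both arrays 2 had too few. The T cell and NK cell list at 6 h turned to 0.0058 with the floor at the 25th percentile, to 0.17 with it at the 60th, and to 0.0052 over members above the floor on both arrays. The clock list at 18 h had a mean of -0.15, and the glucocorticoid list at 18 h a median of -0.0281 without shared genes, an alternative chosen after seeing the data. Among genes named or leading a list, 158 differences passed 2-fold, and 74 of them did so under every alternative in which they could be computed. Hspa4 at 6 h turned to 0.0545 with all probe sets averaged, and without marked probe sets Cd36 at 6 h turned to 0.65 and Zap70 at 90 h to 0.05. Signal near background limits the arrays most for decreases, where the floor hides how far down a dim gene lay.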

Other observations

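Some lists held single genes with large differences while their medians stayed inside the random range. F3, which encodes tissue factor and starts coagulation, was 4.92-fold higher at 6 h, 3.21-fold higher at 18 h and 1.79-fold lower at 90 h, while the complement and coagulation list as a whole had medians of 0.02 and -0.04 at 6 and 18 h. Among endothelial markers, with medians of -0.07, -0.12 and -0.10 at the 3 times, Lyve1 was 2.96-fold and Edn1, endothelin 1, 2.09-fold higher at 6 h. Kdr, a receptor of vascular endothelial growth factor, was 2.46-fold lower. In the matrix list at 6 h, whose median was -0.01, Lox was 2.93-fold, Ccn1 2.66-fold and Ccn2 2.22-fold higher, and Tcf21 at least 2.32-fold lower. Mgst3, a microsomal glutathione transferase, was 2.30-fold higher at 18 h, but its log2 difference was 0.60 with its probe sets averaged. Adm, adrenomedullin, was at least 3.67-fold higher at 6 h.

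The next lists, of alveolar type I cells, ciliated cells, platelets and ribosomal proteins, stayed inside the random range at all 3 times. Alveolar type I markers had medians of -0.02, -0.06 and -0.17, with 10 of 12 genes not above 0 at 90 h. Ciliated cell markers had medians of -0.23, -0.14 and -0.05 in 5 genes, and platelet genes -0.23, -0.32 and -0.20 in 5. Ribosomal protein genes had medians of -0.20, -0.04 and -0.05, with none of 15 above 0 at 6 h.

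In the paragraphs that follow, the tests of an off unexposed array, of white blood cells and lymphocytes, and of the glucocorticoid list against fat were chosen only after the results were seen. Conditions of 3 tests were also changed after values had been seen. The standard errors given are over the genes of a set on the same arrays. They hold no variation between pools, and genes of a set need not vary independently. A first test of fat used genes of the adipocyte list itself, had a median of 0.75 and met its condition, and was dropped as circular for genes outside the lists, whose values had not been looked at. The test of all white blood cells was first written without its condition on macrophages, and in that form its value met the condition. The test of lymphocytes gained its condition on the lower floor once the sign under that floor was known, and its median alone met the earlier condition.

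The fasting and glucocorticoid list and the adipocyte list were both higher at 6 h. An unexposed array that lies low cannot be the whole cause, since the glucocorticoid list differed as much between 6 and 90 h (median 1.13) as between 6 h and unexposed (1.03). Fat tissue taken with the 6 h lungs may have raised the adipocyte genes, and this remains open, because 6 adipose tissue genes from outside the lists had a median of 0.0119 with a standard error of 0.25, with Pnpla2 alone past 2-fold. The glucocorticoid list without adipocyte genes had a median of 1.06 (standard error 0.30) beside 0.75 for the adipocyte list, too close to rule fat out or in. The exposure itself, the stress and fasting of handling, or another hour of day at collection was not tested apart from these. The hour is not given and may differ between pools.

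Nr1d1 and Dbp were lower in the 18 and 90 h pools. An unexposed array that lies high cannot be the whole cause for Nr1d1, which differed by 2.11 log2 units between the exposed pools at 6 and 90 h, but stays open for Dbp, lower at 6 h too, with at least 0.107 between 6 and 90 h, or at least 0.87 with the floor at the 25th percentile, and the 90 h pool at the floor in both. For another hour of day at collection as a candidate explanation, clock genes that peak opposite to Nr1d1, Arntl, Npas2, Clock and Nfil3, exceeded those that peak near it, Nr1d2, Per3 and Tef, by a mean of 1.11 (standard error 0.26) in the lower of the 18 and 90 h pools and 1.34 in the other. This is consistent with a shift in phase, but an effect of HDI on the clock would look alike, and the design cannot part them.

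B cell, MHC class II and interferon lists were lower at 6 h. A smaller share of all white blood cells in the 6 h pool is a candidate explanation. 12 genes used by all white blood cells had a median of -0.69 (standard error 0.19), with Ptprc 2.57-fold lower, but the macrophage list stood at -0.05, with members on both sides (Mpeg1 2.05-fold lower, or -0.52 in log2 with its probe sets averaged, Fabp4 2.74-fold higher), and at -0.13 (standard error 0.12) without Fabp4 and Lpl, which it shares with the adipocyte list, so it stays open. A smaller share of lymphocytes would lower T cell markers too, and their median was -0.36, but 0.01 with the floor at the 25th percentile, so this could not be settled either. A biological explanation, such as lymphocytes leaving the lung after exposure, was not tested apart from these.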
